A study of Mus musculus with 6 samples.

How the data were processed

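Total RNA of mouse embryonic fibroblasts was sequenced in 6 libraries, 3 with the genotype label Ufl1-KO and 3 controls labelled NC, an abbreviation the labels do not spell out. The deposited tables give 1 column per library, as estimated counts per gene and as FPKM. The submitters' processing notes list fastp 0.20.1, STAR 2.7.7a and featureCounts 2.0.0, and the builds mm10, hg38 and GRCh38, without saying what each was used for. The annotation release, the strand setting and the tool behind the fractional values are not given in the sources used here.

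The deposited estimated counts are not normalised. Between 7.29% and 8.09% of the 22274 rows in a library held a value more than 0.001 from a whole number, so the values were rounded before testing. The deposited FPKM values scale the same counts by gene length and by the library total, and the ratio of count to FPKM between libraries follows the ratio of the totals. Rows carry a gene symbol and no other identifier. Of the rows, 1225 name no gene and were left out of library sizes and tests. They held 0.594% to 0.661% of the counts. Another 928 names stand on more than 1 row. These rows were tested separately, and a list member on several rows was used only where a single row had a mean count of at least 10. Some symbols are in the human style (UFM1, COL6A3, SEC61A1) and are printed as the files give them. Of the 21049 named rows, 16473 match a symbol of the mouse annotation GENCODE M21 exactly and 18115 match it in any case. Counts of genes with close copies, such as ribosomal protein genes with their many processed pseudogenes, are uncertain where the counting could split or share reads. Counts of overlapping and antisense genes are uncertain too, since no strand setting is given.

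Gene counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with genotype as the only term. Scaling was by TMM, low counts were removed by filterByExpr, and p-values were two-sided with Benjamini-Hochberg adjustment at a threshold of 0.05. The filter left 12580 genes. Log2 fold changes are Ufl1-KO over NC with their standard error (SE), taken from the fold change and its F statistic. CPM values use TMM-scaled totals and are given as mean ± SD over 3 libraries per group. The 29 gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over all lists with a tested member. Each was repeated with the correlation estimated from the data, and with the rotation test fry. The lists, the tests and the alternatives were fixed before the data were examined.

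The rule for named genes was fixed at the same time. It took genes past the threshold with no overlap of log2 CPM between the groups and an average log2 CPM of at least 2. Ufl1, predicted or unnamed genes and pseudogenes were left out. Of these, the 13 with the largest positive and the 13 with the largest negative log2 fold change were named. The rule added up to 4 members with the smallest p from each list, all UFMylation genes and the sex-linked genes. Some genes the rule takes are counted in their lists, and their single values are not reported here. Genes named as exceptions within a list, or in the closing section, fall outside this rule and were chosen after their values were seen.

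The alternatives were DESeq2 size factors, upper-quartile scaling or library size alone in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, and a CPM of at least 1 in 3 libraries. The FPKM values were tested with limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.1, and on log2(FPKM + 1) without a filter. Further fits used the replicate number as a block, left out each library in turn, or tested against a fold change of 1.5. Intervals of medians are 95% bootstrap intervals over genes from 2000 draws. They treat genes as independent and do not measure the spread between libraries. Figures and summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

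Total counts ran from 15887011 to 21831860 per library. The fit was tested on simulated data with the mean of each gene over all libraries, their sizes and spread, and most genes left unchanged. In that simulation of Ufl1-KO against NC, with 12481 genes tested, 65.7% of genes changed 1.5-fold were recovered, 91% of those changed 2-fold and 97% of those changed 4-fold. Of the 12355 unchanged genes, 0.0405% were called. Only 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, besides a list of 25 raised 1.5-fold. In the real data 66.0% of genes were called, so these shares do not give the recovery or false calls there.

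Sets of genes described in the closing section (6 families picked by name) were chosen after values were seen. Their name patterns were narrowed once, also after values were seen, to leave out some assembly factors and other proteins that only share a name stem. Other assembly factors still match, namely Psmd5, Psmd9 and Psmd10 of the proteasome and Cox7a2l of the respiratory chain. The test of the respiratory chain in the closing section uses the patterns from before the narrowing.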

Results

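RNA sequencing compared mouse embryonic fibroblasts (MEFs, cultured connective tissue cells from embryos) labelled as Ufl1 knockouts with control MEFs labelled NC, in 3 libraries each. Ufl1 encodes the ligase that attaches the small ubiquitin-like protein UFM1 to target proteins, a modification called UFMylation that acts largely at the endoplasmic reticulum (ER). The series title speaks of knockdown and of 24 h of hypoxia. The labels of the single libraries name the genotype and no oxygen condition, so the libraries are compared by genotype label, and no comparison of oxygen levels is made. The Ufl1-KO libraries held 21831860, 17472432 and 20812728 counts, and the NC libraries 17579470, 19779066 and 15887011 counts. Replicates differed by more than sampling noise in every pair, with a chi-square per gene of 2.51 or more, so no library was a copy of another. Nothing in the labels says that replicates came from separate cultures. The p-values then measure only the spread between these libraries, which may be technical. The labels also name no cell line or clone, so a difference between lines cannot be told apart from genotype in any result below.

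Ufl1 mRNA was low in all 3 Ufl1-KO libraries, at 3.82 ± 0.76 CPM against 25.6 ± 2.33 CPM in NC (SD, n = 3 each). The counts were 71, 69 and 102 in Ufl1-KO and 382, 497 and 396 in NC. The log2 fold change was -2.75 (SE 0.15, edgeR adjusted p = 1.59e-06), which left 14.9% of the NC level. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 libraries against 3 allow. Ufl1 lies on chromosome 4 at 25248600 to 25281821 on the minus strand (mm10, GENCODE M21), where it is annotated as a protein-coding gene. Which part of it was altered is not given in the sources used here, so the remaining counts say nothing of the protein.

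The other genes of the UFMylation pathway changed in both directions. Of 8 measured, 5 rose and 3 fell, and the counts were the same when adjusted over the list alone. UFM1 itself rose from 22.6 ± 2.02 to 45.3 ± 2.39 CPM (log2 fold change 1.00, SE 0.09), and the adaptor Ddrgk1 (0.55, SE 0.08) and the conjugating enzyme Ufc1 (0.33, SE 0.08) rose less. The protease gene Ufsp1 rose by 1.75 (SE 0.42) from a low level of 0.541 ± 0.332 CPM. Odr4, Ufsp2 and Cdk5rap3 had log2 fold changes of -0.62, -0.38 and -0.32. As a list the 8 genes were not called against other genes (camera adjusted p = 0.141), while fry, which asks only whether the genes move one way on balance, gave an adjusted p of 0.00134. In the 3 FPKM fits Ufsp2 was the 1 of the 3 lower genes still called, with adjusted p from 0.0575 to 0.0978 for Odr4 and from 0.165 to 0.215 for Cdk5rap3. The call for Cdk5rap3 also ended with library size scaling (adjusted p = 0.259) and without any 1 of Ufl1-KO replicates 1 and 2 and NC replicates 2 and 3 (adjusted p from 0.0861 to 0.1).

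**Figure D1:**
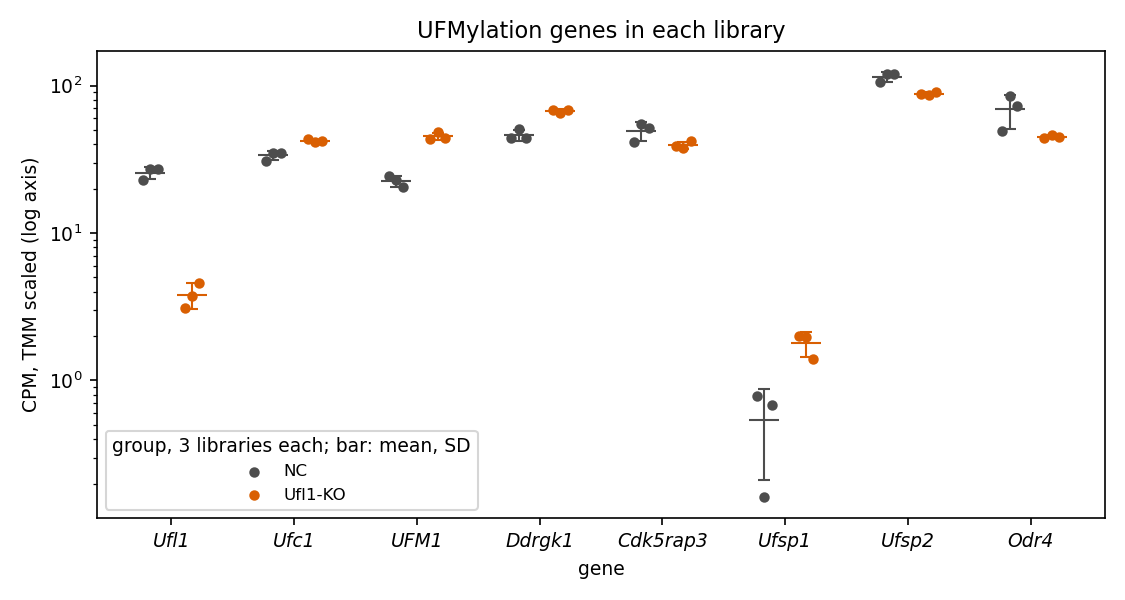
CPM of 8 UFMylation genes (log axis) in each library, with NC in grey and Ufl1-KO in orange; points are libraries and bars the mean and SD of 3. Ufl1 lies at 3.08 to 4.6 CPM in Ufl1-KO and at 22.9 to 27.0 CPM in NC, and UFM1 and Ddrgk1 lie higher in every Ufl1-KO library.

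Across the transcriptome, 4146 genes were higher and 4163 lower in Ufl1-KO, together 66.0% of the 12580 tested. Among them 915 were at least 2-fold higher and 1265 at least 2-fold lower. Against a fold change of 1.5 as the null, 1240 genes were higher and 1604 lower. Groups did not overlap for 71.2% of genes, where chance gives 10% for 3 libraries against 3. With library size in place of TMM, 5471 genes were higher and 3191 lower, because the median log2 fold change of all genes then stood at 0.184 instead of 0.007. Changes below are relative to the TMM scale.

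The largest increases included 2 members of the Ly6 family of surface proteins. Ly6c1 rose from 3.71 ± 0.53 to 53.7 ± 5.33 CPM (14.5-fold, log2 SE 0.13) and Ly6a rose 6.7-fold. Prl2c2, a proliferin of the prolactin family, rose 14.2-fold, and the mitochondrially encoded Mtnd3 rose 10.1-fold. Cmpk2, an interferon-induced nucleotide kinase, rose 9.13-fold, and Il18rap, a subunit of the interleukin-18 receptor, rose 9.1-fold. Also among the 13 were Pcolce2 (7.76-fold), Ca8 (7.57-fold), Gmppb, which makes GDP-mannose (7.5-fold), the transcription factor gene Foxa2 (6.98-fold), Parm1 (6.69-fold), ZNF213 (6.13-fold) and Syt12 (6.11-fold).

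The largest decreases were led by genes of the extracellular matrix. Fmod, encoding the collagen-binding proteoglycan fibromodulin, fell from 16.9 ± 2.0 to 0.503 ± 0.0335 CPM (33.2-fold lower, log2 SE 0.18). Thsd4 was 30-fold lower, Postn (periostin) 21.6-fold lower and Col14a1, a fibril-associated collagen, 20-fold lower. Pglyrp3 was 18.8-fold lower, the water channel gene Aqp1 17.8-fold lower, Pgm5 16-fold lower and the keratin gene Krt7 15.6-fold lower. Megf6 (15.1-fold), Ca9 (15-fold), the acute phase gene Saa3 (14.5-fold), the chemokine gene Ccl20 (14.4-fold) and Nxph1 (13.9-fold) completed the 13.

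Targets of the hypoxia-inducible factors (HIFs) were mostly lower in Ufl1-KO. Of 32 HIF targets outside glycolysis, 28 fell, 1 rose and 3 did not pass the test, with a median log2 fold change of -0.79. Adjusted over the list alone, 29 fell and 1 rose. Ca9, a carbonic anhydrase used as a hypoxia marker, fell from 66.0 ± 5.48 to 4.4 ± 0.295 CPM (log2 fold change -3.91, SE 0.11). Ca12, another carbonic anhydrase, fell from 352 ± 29.9 to 110 ± 2.82 CPM, the glycogen branching enzyme Gbe1 from 403 ± 14.3 to 158 ± 7.06 CPM and Ndrg1 from 5390 ± 336 to 2370 ± 62.6 CPM. The member that rose was Pfkfb4 (log2 fold change 0.94, SE 0.12). The list was lower than other genes by camera (adjusted p = 2.6e-11) but not with an estimated correlation (adjusted p = 0.0641). With library size scaling 2 members rose and 24 fell, and without NC replicate 1 the counts were 2 and 29.

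Among 18 glycolysis genes, 11 fell, 2 rose and 5 did not pass the test, the same counts as when adjusted over the list alone, with a median log2 fold change of -0.46. The glucose transporter Slc2a3 fell from 174 ± 22.3 to 41.7 ± 0.994 CPM (-2.06, SE 0.10). Aldoc (-1.51, SE 0.09), Eno2 (-1.61, SE 0.14) and Gpi (-1.11, SE 0.08), which encode glycolytic enzymes, were lower too. The lactate exporter Slc16a3 (0.92, SE 0.20) and Pfkl (0.26, SE 0.06) were the 2 that rose. Gapdh and Eno1 were not analysed, since each name stands on several rows. Camera gave an adjusted p of 0.00126, and an adjusted p = 0.107 with an estimated correlation. That estimate was -0.0147, below the preset 0.01, so a higher correlation between members is not what ended the call. With library size scaling, 5 members rose and 11 fell.

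Of 8 regulators of the HIF pathway, 3 fell, 2 rose and 3 did not pass, also when adjusted over the list alone. Vhl, whose product targets HIF for degradation, fell (-1.11, SE 0.08), and so did Arnt, the partner subunit of HIF (-1.16, SE 0.10), and Epas1, which encodes HIF-2α (-1.01, SE 0.18). Cited2, a HIF-inducible inhibitor of HIF transactivation, rose (0.93, SE 0.14). The list as a whole had a median of 0.05, a mean of -0.19 and a camera adjusted p of 0.713. With library size scaling and in each FPKM fit 4 rose and 3 fell, with a median of 0.22 to 0.23.

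**Figure D2:**
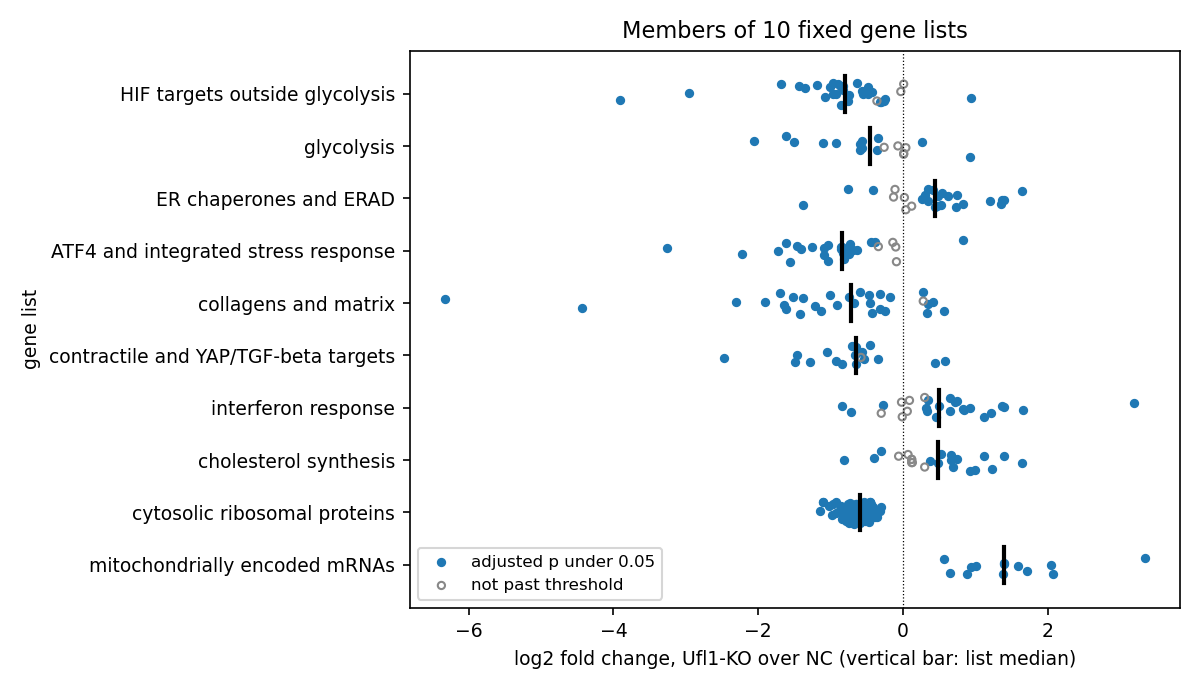
Log2 fold change of Ufl1-KO over NC for each member of 10 fixed gene lists; filled points passed an adjusted p of 0.05, open points did not, and vertical bars are list medians. Medians lie from -0.84 for the ATF4 list to 1.39 for the mitochondrially encoded mRNAs.

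Genes of ER protein folding and ER-associated degradation were mostly higher in Ufl1-KO. Of 27 measured, 19 rose, 3 fell and 5 did not pass, also when adjusted over the list alone, with a median log2 fold change of 0.44. Hyou1, an ER chaperone of the Hsp70 family, rose from 67.7 ± 4.94 to 212 ± 11.6 CPM (1.65, SE 0.08). Creld2 rose from 18.3 ± 1.4 to 47.3 ± 2.75 CPM and the disulfide isomerase gene Pdia6 from 180 ± 2.46 to 300 ± 5.47 CPM. The 3 that fell were Ero1a, an ER oxidase that is also induced by hypoxia (-1.38, SE 0.09), and the stress sensors Atf6 (-0.76, SE 0.08) and Ern1 (-0.41, SE 0.10). By camera the list had an adjusted p of 0.000384, and an adjusted p = 0.417 with an estimated correlation. In NC replicate 1, which stood apart from the other NC libraries, the list lay 0.15 (log2 median) above NC replicates 2 and 3, with 20 of 27 members above, and without that library 19 rose and 4 fell.

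Genes of the ATF4 branch of the integrated stress response went the other way. Of 29 measured, 24 fell, 1 rose and 4 did not pass, also when adjusted over the list alone, with a median of -0.84. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 200 ± 9.79 to 60.3 ± 3.78 CPM (-1.73, SE 0.07) and asparagine synthetase Asns from 154 ± 8.79 to 57.8 ± 1.55 CPM (-1.41, SE 0.07). Fgf21, a secreted stress hormone, fell 9.54-fold from 11.3 ± 1.68 CPM, and the seryl-tRNA synthetase gene Sars1 fell 2.06-fold. The transcription factor genes Atf4 (-1.56, SE 0.10) and Ddit3 (-2.22, SE 0.16), chosen after their values were seen, were lower as well. Wars1, a tRNA synthetase gene that is also interferon-induced, was the 1 that rose (0.83, SE 0.12). Camera gave an adjusted p of 2.18e-09, and an adjusted p = 0.417 with an estimated correlation. In NC replicate 1 the same list lay 0.30 (log2 median) above NC replicates 2 and 3, and without that library the median against NC was -0.71.

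**Figure D3:**
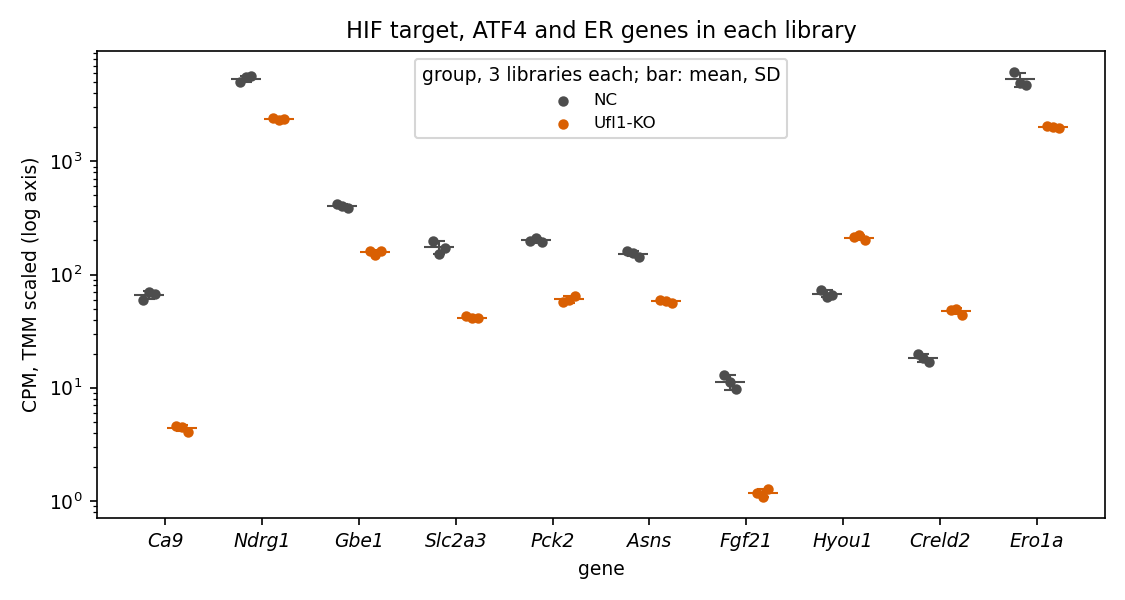
CPM (log axis) of 10 genes from the HIF target, glycolysis, ATF4 and ER lists in each library, with NC in grey and Ufl1-KO in orange; points are libraries and bars the mean and SD of 3. Hyou1 and Creld2 lie higher in every Ufl1-KO library, and the other 8 genes lie lower.

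Collagen and matrix genes formed another group that fell. Of 30 measured, 24 fell, 5 rose and 1 did not pass, with a median of -0.72, and 24 fell and 6 rose when adjusted over the list alone. Postn fell from 342 ± 24.3 to 15.8 ± 0.65 CPM (-4.43, SE 0.08), Col3a1 from 1890 ± 205 to 502 ± 21.9 CPM, Col12a1 from 607 ± 48.2 to 193 ± 7.33 CPM and COL6A3 from 79.9 ± 3.35 to 16.2 ± 0.168 CPM. The 5 that rose were Col11a1, Mmp13, Mmp14, Timp2 and Timp3, with log2 fold changes of 0.27 to 0.57. The list lay lower than other genes by camera (adjusted p = 9.2e-13), but not with an estimated correlation (adjusted p = 0.107).

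Contractile genes and targets of YAP and TGF-beta followed, with 15 of 18 lower and 2 higher (median -0.65), or 16 and 2 when adjusted over the list alone. Calponin Cnn1 fell from 63.1 ± 3.8 to 11.4 ± 1.17 CPM (-2.47, SE 0.10), Tgfb2 fell 2.82-fold, Tgfbi 2.75-fold and Thbs1 1.79-fold. The 2 that rose were ACTA2 (0.44, SE 0.09), smooth muscle actin, and Ankrd1 (0.58, SE 0.08). In the camera test the adjusted p was 0.000864, or an adjusted p = 0.107 with an estimated correlation. Here too the estimate (-0.00763) lay below the preset 0.01, so a higher correlation is not what ended the call.

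Interferon response genes were higher in Ufl1-KO for 18 of 27 members and lower for 3, also when adjusted over the list alone, with a median of 0.50. Cmpk2 rose from 2.38 ± 0.32 to 21.7 ± 1.33 CPM (3.19, SE 0.13), Parp14 rose 3.16-fold, the transcription factor gene Stat2 2.63-fold and the antiviral gene Rsad2 2.58-fold. The 3 that fell, Psmb9 (-0.84), Tap1 (-0.72) and B2m (-0.27), serve antigen presentation on MHC class I. The list was higher by camera (adjusted p = 1.27e-05), with an adjusted p = 0.428 with an estimated correlation. The NF-kB and cytokine list was split, with 7 of 17 higher, among them the chemokines Ccl2 (2.28, SE 0.10) and Cxcl5 (2.44, SE 0.16), and 9 lower, among them Ccl20 (-3.84, SE 0.23) and the NF-kB inhibitor Nfkbia (-1.03, SE 0.11). The counts were the same when adjusted over the list alone (camera adjusted p = 0.993), while with log2(FPKM + 1) values 9 were higher and 8 lower of 20 tested.

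Cholesterol synthesis genes rose for 13 of 23 members and fell for 3, also when adjusted over the list alone, with a median of 0.49. Idi1 (1.40, SE 0.08), Cyp51a1 (1.23, SE 0.07) and Hmgcs1 (0.99, SE 0.08) encode enzymes of the pathway. The 3 that fell were Lss, Pmvk and Stard4. Camera gave an adjusted p of 0.00121, and an adjusted p = 0.296 with an estimated correlation.

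All 13 mitochondrially encoded mRNAs rose, also when adjusted over the list alone, with a median of 1.39. They made up 1.85% to 1.89% of counts in the Ufl1-KO libraries and 0.901% to 0.991% in the NC libraries. Mtnd1 rose from 215 ± 23.7 to 903 ± 67.4 CPM, Mtnd4 from 242 ± 7.17 to 634 ± 45.4 CPM and Mtnd5 from 194 ± 19.8 to 584 ± 37.5 CPM, all subunits of respiratory complex I. This was the only list whose call held with an estimated correlation (camera adjusted p = 3.7e-15, or 0.0428 with the estimate).

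Cytosolic ribosomal protein mRNAs fell for all 75 members measured, also when adjusted over the list alone, with a median of -0.59. Fau fell from 600 ± 60.1 to 272 ± 11.4 CPM, Rps19 from 267 ± 33.7 to 136 ± 2.79 CPM, RPS16 from 346 ± 43.5 to 171 ± 12.6 CPM and RPL22 from 233 ± 33.2 to 109 ± 5.24 CPM. Camera gave an adjusted p of 4.36e-10, and an adjusted p = 0.627 with an estimated correlation. NC replicate 1 was lower than NC replicates 2 and 3 in this list too, by a median of -0.32 with 0 of 75 members above, and without it the median against NC was -0.69.

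Cell cycle genes moved in both directions. Of 24 S phase genes 10 fell and 6 rose, with the ribonucleotide reductase subunit Rrm2 (1.47, SE 0.07) and cyclin Ccne1 (2.02, SE 0.19) higher and E2f1 (-1.41, SE 0.08) and Pola1 (-0.72, SE 0.06) lower. Of 24 G2/M genes 9 rose and 5 fell, with Ccnb1 (0.93, SE 0.09), Kif20a (0.78, SE 0.07) and Kif23 (0.39, SE 0.06) higher and Aurkb (-0.60, SE 0.08) lower. Among 21 p53 targets 10 rose and 7 fell, with Perp (1.35, SE 0.08), Eda2r (1.26, SE 0.12) and Ccng1 (1.12, SE 0.09) higher and the cell cycle inhibitor Cdkn1a (-0.71, SE 0.06) lower. Counts for these 3 lists were the same when adjusted over the list alone. Camera adjusted p-values were 0.713, 0.414 and 0.414. With library size scaling, 15 G2/M genes rose and 3 fell, and the S phase median turned from -0.13 to 0.05. In NC replicate 1 the G2/M list lay below NC replicates 2 and 3 by a median of -0.23, with 1 of 24 members above. Without that library 12 p53 targets rose and 7 fell, and their median went from 0.14 to 0.41.

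Autophagy and lysosome genes rose for 8 and fell for 9 of 25, with GABARAPL1 (-1.39, SE 0.09) and Calcoco1 (-1.10, SE 0.10) lower and Cln3 (1.41, SE 0.15) higher. This balance depended on scaling, with 12 higher and 4 lower by library size, 12 and 6 in each FPKM fit, and a median that turned from -0.09 to 0.09 by library size. NRF2 targets rose for 7 and fell for 6 of 18, or 8 and 7 when adjusted over the list alone, with Pgd (1.56, SE 0.10) and Taldo1 (0.80, SE 0.07) of the pentose phosphate pathway higher and Gstm1 (-1.18, SE 0.08) and Abcc1 (-0.83, SE 0.05) lower. Heat shock and immediate early genes rose for 6 and fell for 5 of 16. Egr1 (-2.32, SE 0.09), Fos (-2.27, SE 0.14) and Ier3 (-0.95, SE 0.06) fell and the chaperone gene Hsph1 (1.34, SE 0.11) rose. Counts for the autophagy and heat shock lists were the same when adjusted over the list alone. Camera adjusted p-values were 0.795, 0.847 and 0.558. In NC replicate 1, 15 of the 16 heat shock and immediate early genes lay above NC replicates 2 and 3. Without that library 9 of these genes rose and 6 fell, and their median went from 0.14 to 0.43.

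Of 11 fibroblast markers, 7 fell and 2 rose (median -0.52, camera adjusted p = 0.216). Vim, the intermediate filament vimentin, fell from 4420 ± 544 to 2280 ± 65.7 CPM, Pdgfra 2.21-fold, Pdgfrb 1.86-fold and TWIST1 1.49-fold. Epithelial markers were lower for 3 of 6 and higher for 1, with Krt19 at 970 ± 24.1 CPM in NC and 537 ± 14.4 CPM in Ufl1-KO, Krt14 2.11-fold lower, Cldn3 2.19-fold lower and Cdh1 1.63-fold higher. Blood and macrophage markers fell for 4 of 4, namely Cd68 (-0.84), Cd74 (-0.89), Csf1r (-0.94) and Lyz2 (-0.79), all below 28 CPM in NC. The call for Lyz2 ended without Ufl1-KO replicate 1 (adjusted p = 0.118), Ufl1-KO replicate 2 (0.107) or NC replicate 3 (0.127), with library size scaling (0.0819) and in the FPKM fits (0.0581 to 0.0985). The number lower was then 3 by library size and 3, 3 and 2 in the FPKM fits, where more of these markers were tested. Of 4 endothelial markers Pecam1 fell, from 0.917 ± 0.263 CPM in NC, while Kdr (0.23), Eng (-0.23) and Tek (-0.18) did not pass.

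Adipocyte markers fell for 2 of 5, Fabp4 (-2.85, SE 0.16) and Lpl (-0.60, SE 0.12), and rose for 2, Pparg (0.87, SE 0.25) and Cebpa (1.68, SE 0.48). Cartilage and bone markers fell for 2 of 4, Acan (-1.61) and Sp7 (-1.65), and Sox9 rose (0.70, SE 0.27), while Runx2 (-0.12) did not pass. Neural and glial markers fell for 3 of 6, among them Mbp (-1.14) and Map2 (-0.47), and Tubb3 rose (1.74, SE 0.14). The call for Sox9 was not firm, ending without Ufl1-KO replicate 1 (adjusted p = 0.0906), Ufl1-KO replicate 2 (0.112), Ufl1-KO replicate 3 (0.0881), NC replicate 2 (0.126) or NC replicate 3 (0.158), and in the DESeq2 Wald test (0.108). With library size scaling and in each FPKM fit 2 neural and glial genes were higher and 1 lower. Without NC replicate 1, 2 of them were higher and 3 lower. Without Ufl1-KO replicate 3, 1 adipocyte gene was higher and 2 were lower, of 4 tested. The call for Map2 ended with library size scaling (adjusted p = 0.0548). No skeletal muscle marker had enough counts to be tested. Camera adjusted p-values of the tested marker lists ran from 0.216 to 0.929, and counts in each were the same when adjusted over the list alone.

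Hox genes, which mark position along the body axis, were lower for 11 and higher for 8 of 27, also when adjusted over the list alone (camera adjusted p = 0.847). The number lower was 6 without Ufl1-KO replicate 1, Ufl1-KO replicate 2 or NC replicate 3, 7 without Ufl1-KO replicate 3 or NC replicate 2, and 5 with library size scaling. Hoxb9 (-0.96, SE 0.08) fell, and Hoxd8 (1.44, SE 0.14), Hoxa7 (1.20, SE 0.13) and Hoxb7 (0.89, SE 0.11) rose. Genes of the Y chromosome were expressed in both groups. Ddx3y was at 70.1 ± 3.27 CPM in Ufl1-KO and 47.4 ± 7.91 CPM in NC, Kdm5d (0.42, SE 0.10) was also higher, Eif2s3y (-1.11, SE 0.18) was lower and Uty (0.03, SE 0.08) did not pass. Counts for this list of 4 tested genes, 2 higher and 1 lower, were the same when adjusted over the list alone (camera adjusted p = 0.847).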

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

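Of the rows that name no gene, which entered no test, 74 had a mean of at least 1 CPM. In 4 of them every Ufl1-KO library lay above every NC library with a mean at least 2 times higher. In 11 the reverse held. Chance alone puts 5% of rows without overlap in each direction, before any demand on fold. The 4 rows lie close to that share and the 11 lie above it, and the chance share with the fold demand was not estimated. Among the named genes tested, groups did not overlap for 71.2%, so the chance share is not the rate seen across the transcriptome.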

How the results depend on the processing

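All alternatives below were chosen before the data were examined. Ufl1 stayed lower under all 17, with log2 fold changes from -2.91 to -1.93. Counts of genes stayed within 1.5 times of 4146 higher and 4163 lower, except against a fold change of 1.5 (1240 higher, 1604 lower), a stricter null by construction. Leaving out 1 library gave 3545 to 4787 higher and 3654 to 4757 lower, most without NC replicate 1. With an estimated correlation the calls for HIF targets (adjusted p = 0.0641), glycolysis (0.107), ER (0.417) and ATF4 (0.417) ended. Of the other lists 1 was called instead of 6. For glycolysis and the contractile list the estimate lay below the preset 0.01, so a higher correlation did not end those calls. For UFMylation the estimate was 0.0104, near the preset, yet the unadjusted camera p went from 0.0552 to 0.128. The version with an estimate is thus stricter apart from the correlation itself. A call lost in that version does not by itself show that members are correlated. Fry, a test of another question, called UFMylation (0.00134) and 15 of the others. Under all scalings, filters and left-out libraries those 4 lists kept their calls and directions. UFMylation members lower went from 3 to 1 in each FPKM fit, HIF targets higher from 1 to 2 with library size scaling and in each FPKM fit (1 to 2 over left-out libraries), and glycolysis members higher from 2 to 5 with library size scaling, log2(FPKM + 1) and log2(FPKM + 0.1); apart from the scaling shift the cause was not tested.

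Of 137 named genes besides Ufl1 over 17 settings, 2278 values kept direction and side of the threshold, 38 lost the call, 2 gained it and 6 changed sign, all 6 in genes not called. These were Tek (0.02 with log2(FPKM + 0.1); -0.58 to 0.08 over left-out libraries), Runx2 (0.06 with library size scaling; -0.28 to 0.01) and Uty (-0.02 to 0.07). Lists that were not called changed sign too: NF-kB and inflammatory cytokines (adjusted p = 0.949 with upper-quartile scaling, 0.817 to 0.955 over left-out libraries), endothelial and neural markers (both 0.988 with the CPM filter), heat shock (0.351 to 0.955) and cartilage and bone (0.711 to 0.912); the cause was not tested.

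The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.021, -0.135 and 0.044, and not every library correlated best with its own number. With the replicate block 3969 genes were higher and 3976 lower, 7843 of them among the 8309 called without it, and no call of a named gene or list changed. At the depth, number and spread of these libraries 65.7% of simulated 1.5-fold changes were recovered, with 12355 of the simulated genes left unchanged. Depth alone was not varied.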

Other observations

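Among 6 gene families picked by name, 4 passed the camera test and none did with an estimated correlation (lowest adjusted p = 0.195). Of their members, 5 synthetase genes also belong to the ATF4 list, and Psmb8 and Psmb9 to the interferon list. All 6 were chosen after values were seen, and the name patterns of 3 were then narrowed; with the wider patterns the medians were 0.37 for 38 proteasome genes, 0.32 for 19 coat genes and 0.04 for 89 respiratory chain genes. Library size scaling put the median of all genes at 0.184, and the 6 medians kept their signs under all 4 scalings. Genes named as proteasome subunits rose for 25 of 37 and fell for 3 (median log2 fold change 0.38, 95% interval 0.22 to 0.57), led by Psmd6 (1.30), Psmb3 (1.06) and PSMC5 (0.94). The 25 include the assembly factors Psmd5, Psmd9 and Psmd10. The camera adjusted p over the 6 families was 0.000899, or 0.195 with an estimated correlation. Psmb9, a subunit of the interferon-induced immunoproteasome, fell (-0.84). Coats of ER and Golgi transport vesicles rose for 12 of 18 and fell for 1 (median 0.32, 0.18 to 0.51), with Sec23b (1.15), Sec13 (1.08) and Sec23a (0.94) highest (adjusted p = 0.00487, or 0.451 with an estimated correlation). Without NC replicate 1, 24 proteasome genes rose and 8 fell, and 12 coat genes rose and 3 fell.

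Fatty acid synthesis and elongation genes rose for 10 of 17 and fell for 2, with Fasn, fatty acid synthase, at 2.24 and the elongase Elovl6 at 1.27 (adjusted p = 0.00851, or 0.195 with an estimated correlation). Their median of 0.45 had an interval of -0.15 to 0.67, and without NC replicate 1 the counts were 10 and 5. Mitochondrial ribosomal proteins rose for 40 of 78 and fell for 10 (median 0.26, 0.16 to 0.35, adjusted p = 0.0196, or 0.51 with an estimated correlation), and without NC replicate 1 for 39 and 20. Nuclear genes of the respiratory chain and ATP synthase were split, 20 higher and 20 lower of 80 (adjusted p = 0.472), or 38 and 9 with library size scaling. Aminoacyl-tRNA synthetase genes fell for 10 of 17 and rose for 3, among them Yars1 (-0.91) and Hars1 (0.81), and the family was not called (adjusted p = 0.0916).

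The tests below of sequencing depth, of genes between the length quartiles of the ribosomal protein genes, of scaling on the mitochondrial and ribosomal genes, of a milder hypoxia, and of NC replicate 1 or a mixture as the whole cause were chosen after the results they measure were seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 8309 genes and, at the preset correlation, 10 lists, of which 1 was called with an estimated correlation. The most that another split called was 0 genes (edgeR; at most 220 at an unadjusted p under 0.05, against 8729 in the real split) and 13 lists. For genes 1 of the 10 splits reached the real number, and for lists 3 did. Every other split mixes Ufl1-KO and NC libraries on both sides, so the difference between the groups adds to the spread within each side. Calls in those splits are therefore not a rate expected by chance, and neither number tests the real split.

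HIF targets outside glycolysis were lower in Ufl1-KO by camera at the preset correlation (adjusted p = 2.6e-11), but not with an estimated correlation (adjusted p = 0.0641). The 4 scalings shift all genes together and put the median of all genes between 0.003 and 0.184, so a wider change in RNA content was not tested. The choice among these scalings is argued against as the cause, since the median of the list was -0.61 or lower under all 4. So is the difference of NC replicate 1 from the other NC libraries as the whole cause, since without it the median was -0.72 (95% interval -0.87 to -0.48) and the list was still called at the preset correlation; the bound set beforehand, a median at least as far from 0 as -0.79, was missed, so a part in the size stays open. A milder hypoxia exposure of the Ufl1-KO cultures may also lower these genes, and it cannot be told apart from genotype because the labels give no oxygen condition per library; of the 50 HIF target and glycolysis genes 39 were lower and 3 higher. An effect of Ufl1 loss on HIF signalling stays open as an untested hypothesis.

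Mitochondrial mRNAs were higher and ribosomal protein mRNAs lower in Ufl1-KO. A length bias is argued against for both, but for the mitochondrial mRNAs over a wide length range only. The 3227 nuclear genes of that range (204 to 1824 bases), ribosomal protein genes among them, had a median log2 fold change of -0.02. No narrower range was tested for the mitochondrial mRNAs. The 547 other nuclear genes between the length quartiles of the ribosomal protein genes (578 to 967 bases) also had a median of -0.02 (95% interval -0.08 to 0.04). The whole length range of the ribosomal protein genes (median 0.01) takes in 67.9% of tested genes and decides nothing. The choice among the 4 scalings is argued against as the cause. Medians were at least 1.38 for the mitochondrial mRNAs and at most -0.41 for the ribosomal protein mRNAs under all 4. The scalings shift all genes together and put the median of all genes between 0.003 and 0.184, so a wider change in RNA content was not tested. On the TMM scale a general rise of the respiratory chain is argued against by the nuclear subunits. Their median was 0.04 (95% interval -0.05 to 0.14, 89 genes by the wider name patterns). With library size scaling it was 0.22, above the bound of 0.2 set beforehand, with 42 higher and 9 lower, so there the rise stays open. The family itself was picked after values were seen. The subunits stood 0.04 above the median of all genes, a difference that the choice of scaling cannot change. Library preparation, which the labels do not describe by group, and an effect of genotype may each contribute and were not tested.

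NC replicate 1 lay 18.0% of the way from the other NC libraries to the Ufl1-KO libraries on the first principal component, which held 84.7% of the variance. On the second component (7.3%) it stood at 28.74, against -13.66 and -9.77 for NC replicates 2 and 3. The Ufl1-KO libraries stood at -4.87 to 0.43 there. NC replicate 1 was thus farther from the other NC libraries on the second component, and past the Ufl1-KO libraries, so it did not differ only by a move towards them. Lower depth is argued against, since its total count of 17579470 lay between those of the other NC libraries. Admixture of Ufl1-KO RNA met the bound set beforehand, a share near that 18.0%. The median implied share was 13.95% (95% interval 8.09 to 22.03) over 64 genes at least 4 times higher in Ufl1-KO. The 147 genes at least 4 times lower gave 22.2% (18.55 to 26.28). Any cause that moves NC replicate 1 along the first component can meet this bound, so it does not single out admixture. As the whole cause admixture is argued against by the ATF4 list, which was lower in Ufl1-KO. In NC replicate 1 that list was higher by a median of 0.30 (95% interval over genes 0.12 to 0.37). The interval is over correlated genes (estimate 0.374) and does not measure the spread between libraries. Among the 64 genes the share was below 5% for 19, Ly6c1 (-1.8%) and Spp1 (-2.2%) among them, and above 30% for 14. An admixture together with another state of that culture may remain.

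Median log2 fold changes by chromosome differed from those of all other chromosomes by up to 0.16 (chromosome 15, lower), and 6 of 20 chromosomes lay outside the 99% range of random gene sets, a difference between the bounds set beforehand of 0.1 and 0.2 that leaves copy number undecided.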
